A study of Rattus norvegicus with 40 samples.

How the data were processed

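Gene expression was measured on 40 Affymetrix Rat Gene 1.0 ST arrays hybridised with liver RNA of Sprague Dawley rats, in 12 groups formed by 3 models (fasted/refed, partial hepatectomy, fetal), 2 treatments (DMSO, rapamycin) and 2 fractions (polysome RNA from sucrose gradients, total RNA). Groups and replicate numbers were taken from the sample labels, which call the arrays of a group biological replicates, with n = 3 livers per group in the adult models and n = 4 in the fetal model. The time point given for the 3 hepatectomy polysome DMSO arrays was that of refeeding, against their titles and their injection field, which name partial hepatectomy. The titles were used: the mean of the mitosis list was 9.82 to 10.25 in these arrays and 5.98 to 6.15 in all fasted/refed polysome arrays. Per the labels' protocols RNA came from pooled polysome preparations. What was pooled is not given in the sources used here, and each numbered replicate was taken as 1 liver. The labels give 100 ng of RNA as the input to labelling for every array.

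The values used were the authors' processed array intensities on a linear scale, 1 value per transcript cluster and array, which the authors had normalized with RMA (robust multi-array averaging, which corrects background, equalises the distributions of the arrays and summarises probes), per the submitters' processing notes. The RMA version, its settings, the set of arrays normalized together and the annotation build are not given in the sources used here. The 28826 rows of values ran from 3.77 to 28447, which shows a linear scale, and they were log2-transformed here with no pseudocount. The median log2 intensity per array was 7.09 to 7.40, with no array apart in scale. Arrays give no read depth, and their number limits the precision. RMA removes any difference between arrays in the total signal, so a change common to all mRNAs of a fraction cannot be seen. No 2 arrays held the same values: the smallest root mean square difference between any 2 was 0.195 on the log2 scale.

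The platform annotation paired 15209 transcript clusters with 1 gene symbol and 306 with several, and 13311 were unnamed here. Symbols were checked through Entrez gene numbers against a RefSeq gene table of the rat assembly GRCr8, used only for names: 15178 matched and 0 symbols changed. Transcript clusters with several symbols were tested but never named. The 10860 transcript clusters tested (10203 genes) carried at least 1 symbol and had a mean log2 intensity over all arrays at or above the 30th percentile of named ones, 6.7. Some of the genes set down for reporting are not reported here.

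Each comparison was fitted with limma 3.58.1 in R 4.3.3 on the group means, with the variance moderated by empirical Bayes with an intensity trend. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the transcript clusters tested, with a threshold of 0.05. Comparisons within a model used the arrays of that model alone, with 8 residual degrees of freedom in adults and 12 in fetuses, and comparisons across models used all 40 arrays, with 28. Within each model and fraction rapamycin was compared with DMSO. The difference of that effect between fractions was tested as an interaction, and its difference between the 3 models as a moderated F-test. Polysome was compared with total RNA within DMSO livers, and the DMSO total RNA of the models with each other. Errors beside log2 changes are standard errors of the fit (SE), and those beside group means are standard deviations (SD).

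Tests, filters, 34 gene lists and the rule for named genes were set in advance. The rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with exactly 1 symbol and no placeholder name. Where none passed, it named the 3 with the smallest p in each direction as values, of which some are left out. It named the 10 smallest p of each F-test, the 5 largest differences each way in the descriptive comparisons, up to 4 members of each list past its threshold, and 18 fixed genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera was repeated with the correlation estimated per list, and limma's fry was run as an alternative that does not compare a list with other genes. Of the 161 camera calls, 5 held with an estimated correlation and 43 under fry. A gene with several transcript clusters was represented by the one with the highest mean. In all, 33 lists had at least 5 tested members, and 1 list was not analysed here. A count adjusted over the list alone repeats the Benjamini-Hochberg step over that list's members.

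Pairing was checked by correlating the deviations of arrays from their group means over transcript clusters. Polysome and total arrays of equal treatment and number were taken as 2 fractions of 1 liver. They correlated at 0.46 to 0.82 (fasted/refed), 0.51 to 0.72 (hepatectomy) and 0.33 to 0.69 (fetal). Fetal DMSO and rapamycin arrays of equal number correlated at 0.42 to 0.75 in all 8 pairs. Their number was taken to pair treatments, for a reason the labels do not give. In adults these ran from −0.62 to 0.39 and −0.07 to 0.28, so adult numbers did not pair treatments. Since different fetal livers correlated as highly, the pairing of fetal fractions was assumed.

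List means per liver were compared by exact 2-sided permutation tests over livers, within each model and, for the adult models together, by permuting within each model, with Benjamini-Hochberg adjustment over 33 lists. With 3 against 3 livers the smallest possible exact p is 0.1. For fetal pairs of equal number the signs of the 4 differences were flipped, with a smallest possible exact p of 0.125. These tests, the fit without both divergent fasted/refed livers, the liver as a random block, 1 weight per model, a fetal-only block and loess scaling for the lists were chosen after seeing the data. The alternatives set before were no filter on dim transcript clusters, a filter at the 50th percentile (8.21), all rows of the table whether named or not, cyclic loess scaling, no intensity trend, array quality weights, all 40 arrays, only the 2 groups or only the arrays of 1 fraction in the fit, the replicate number or the liver as a fixed block, and leaving out each replicate in turn.

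The pipeline was tested on simulated data drawn from the means and spreads of each model, with a correlation of 0.6 between the fractions of a liver, in 5 runs, with 200 genes changed per run by 0.5, 1 or 2 on the log2 scale. Changes of 1 were recovered for 91.9% of genes in the hepatectomy polysome comparison, 68.4% in the fasted/refed and 81.5% in the fetal one. In total RNA the same figures were 89.9%, 70.1% and 77.6%. Changes of 0.5 were recovered for 54.6%, 17.3% and 30.4% of genes in polysome RNA and 52.5%, 22.1% and 29.3% in total RNA. For the interaction of drug and fraction, changes of 1 were recovered for 73.7% after hepatectomy, 31% in the fasted/refed and 50.1% in the fetal model. The share of false calls was 6.84% to 8.45% in the hepatectomy and fetal comparisons of rapamycin and 7.51% and 7.2% in the fasted/refed ones. In fits that pool the 3 models, whose spreads differ, it was 22% and 20.5% for the F-tests, 12.5% for hepatectomy against fasted/refed and 25.3% for fetal against fasted/refed livers.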

Results

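Liver gene expression was measured in Sprague Dawley rats in 3 settings of growth, each with and without rapamycin, an inhibitor of the kinase mTOR. In the fasted/refed model, which stands for growth without cell division, adult rats were fasted for 48 h, injected, and refed for 3 h starting 1 h after the injection. In the partial hepatectomy model, adult rats were injected 1 h before surgical removal of most of the liver and their remaining liver was taken 24 h later, when hepatocytes divide. In the fetal model, fetuses were injected on day 19 of gestation and their livers were taken on day 20. The injection held dimethyl sulfoxide (DMSO), the solvent, or rapamycin at 250 µg per 100 g of body weight in adults and 50 µg per fetus. From each liver, RNA was prepared from polysomes, the fraction in which several ribosomes sit on each mRNA, and from whole tissue (total RNA). The 40 Rat Gene 1.0 ST arrays were read as 20 livers in 12 groups, with n = 3 livers per group in each adult model and n = 4 in the fetal model. The labels' protocol speaks of pooled polysome preparations without saying what was pooled, so that n counts the numbered replicates. The median log2 intensity per array lay between 7.09 and 7.40. Since 100 ng of RNA was labelled for every array and the values were scaled across arrays, a value gives the share of an mRNA within its fraction, and the total amount of mRNA on polysomes was not measured.

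The comparison after partial hepatectomy asked what rapamycin does to polysomal mRNA in proliferative growth of the adult liver. With rapamycin, genes of cell division, serine synthesis and ribosomal proteins were among those that fell in polysome RNA, and some endothelial markers were among those that rose. As whole lists, the mitosis, ribosomal protein and endothelial genes each had an adjusted p of 0.48 with an estimated correlation. Mocos, which encodes the enzyme that activates the molybdenum cofactor of xanthine dehydrogenase and aldehyde oxidase, rose most, by 1.77 ± 0.112 on the log2 scale (SE, n = 3 per group; adjusted p = 2.15e-05). Psat1, an enzyme of serine synthesis, fell by 1.92 ± 0.187 (adjusted p = 0.00095), and Birc5, the mitotic regulator survivin, fell by 1.78 ± 0.265 (adjusted p = 0.00888). Of 10860 transcript clusters tested with limma, 245 rose and 445 fell at an adjusted p under 0.05, among them 88 that rose and 230 that fell by more than 1.5-fold.

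Among the 10 genes with the largest rise in polysome RNA were Popdc2 (log2 change 1.58), Serpina7, which encodes the plasma carrier of thyroxine (1.52), Nr0b2, a nuclear receptor that represses bile acid synthesis (1.51), Kmo, an enzyme of tryptophan degradation (1.30), and Rcan2 (1.25). Inhba, the subunit of activin A, rose by 1.23, Pcp4l1 by 1.16, the transporter gene Slc16a4 by 1.12 and the receptor gene Ror1 by 1.04. The 10 with the largest fall were led by Ccnb2, a B-type cyclin (−2.09 ± 0.436, adjusted p = 0.0257), Cep55, which acts at the last step of cytokinesis (−1.93), Psat1, the kinetochore gene Knstrn (−1.90) and Ect2, an activator of the contractile ring (−1.89). Ccnb1 (−1.88 ± 0.454, adjusted p = 0.0363), Kif20a (−1.88), the kinase gene Aurka (−1.86), Trim59 (−1.79) and Birc5 followed. For each of these 20 genes, all 3 rapamycin livers lay on 1 side of all 3 DMSO livers. Their selection as the largest changes favours this separation. Single livers moved the count: 1687 transcript clusters passed without the polysome array of DMSO 1, 64 without DMSO 2, 98 without DMSO 3, 80 without rapamycin 1, 432 without rapamycin 2 and 57 without rapamycin 3. In that order, 20, 6, 8, 8, 18 and 6 of these genes stayed past the threshold, and Mocos, Kmo, Ror1, Psat1 and Birc5 did so in each of the 6 fits. Cyclic loess scaling moved the share of polysome calls that rose from 35.5% to 43.6%.

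**Figure D1:**
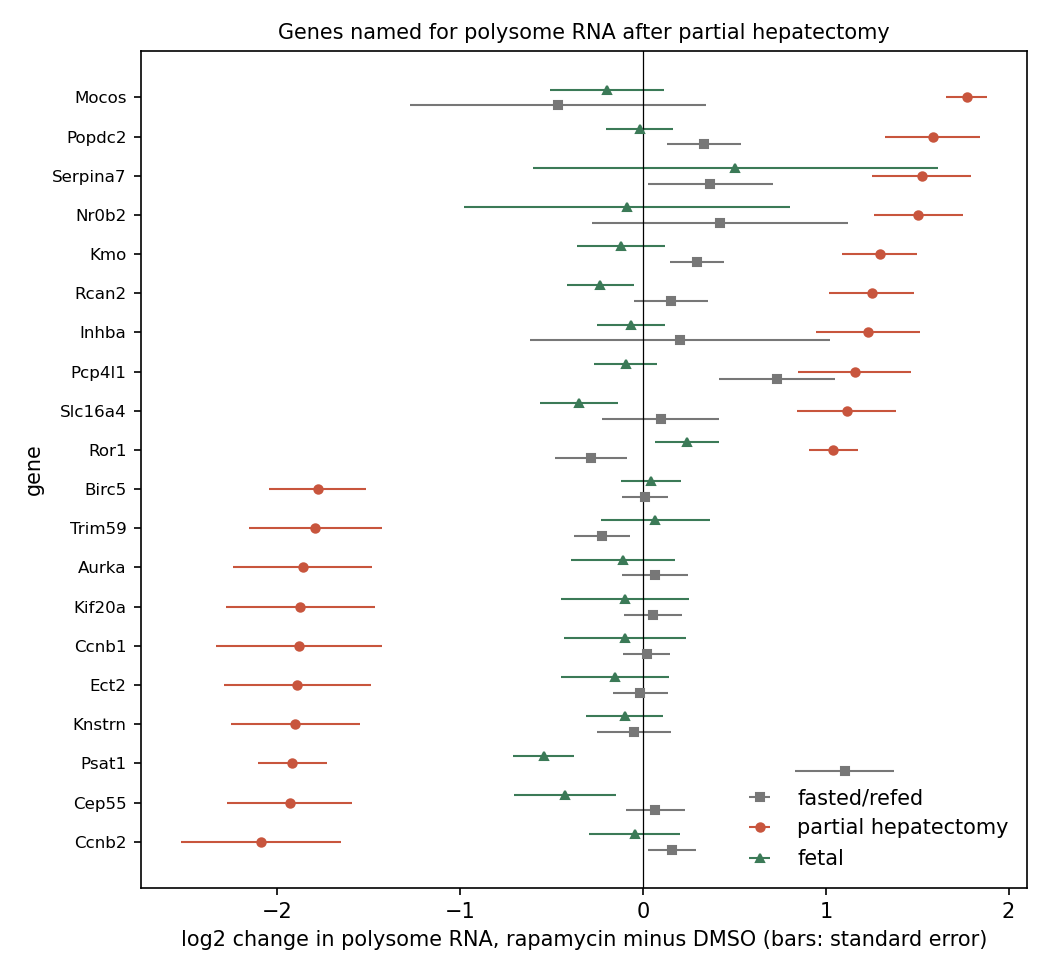
Log2 change in polysome RNA (rapamycin minus DMSO, x axis) of the 20 genes with the largest rise or fall after partial hepatectomy, with points for the estimate in each of the 3 models and bars for its SE (n = 3 livers per group in the adult models, n = 4 in the fetal model). After hepatectomy Mocos lies at 1.77 and Ccnb2 at −2.09, while no gene passed an adjusted p of 0.05 in the fasted/refed or the fetal model.

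Gene lists fixed before the data were examined described these changes by pathway, tested against all other genes with limma's camera at a preset correlation of 0.01. Of 38 mitosis genes, 28 fell (38 adjusted over the list alone), with a median log2 change of −1.41 (camera adjusted p = 3.9e-21; adjusted p = 0.48 with an estimated correlation). Of 39 genes of DNA replication, 8 fell (16 adjusted over the list alone), with a median of −0.54 and Ccna2 (−1.34), Rfc4 (−1.19) and Rrm2 (−1.19) in front (adjusted p = 1.04e-08; adjusted p = 0.48 with an estimated correlation). All 68 ribosomal protein mRNAs were lower on polysomes, with a median of −0.34, and 24 fell (53 adjusted over the list alone), led by Rps12 (−0.92 ± 0.133, adjusted p = 0.00888), Rps15a (−0.81), Rpl34 (−0.74) and Rps19 (−0.71). That list's camera adjusted p was 1.55e-20, and its adjusted p = 0.48 with an estimated correlation. Targets of the transcription factor ATF4, which serve amino acid synthesis and the amino acid response, had a median of −0.30 over 31 genes, of which 6 fell (10 adjusted over the list alone; camera adjusted p = 2.05e-05; adjusted p = 0.48 with an estimated correlation). Besides Psat1 these were led by Phgdh (−1.52, adjusted p = 0.00888) and Psph (−0.98, adjusted p = 0.0186), the other enzymes of serine synthesis, and Trib3 (−1.27, adjusted p = 0.0146). Of 70 mitochondrial ribosomal protein mRNAs, 6 fell (7 adjusted over the list alone), with a median of −0.18 and Mrps22 at −0.73 (adjusted p = 4.62e-05; adjusted p = 0.549 with an estimated correlation). Among 35 proteasome genes only Psma5 (−0.47) fell (0 adjusted over the list alone), and the median was −0.13 (adjusted p = 0.00144; adjusted p = 0.577 with an estimated correlation).

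Lists of markers of cells other than hepatocytes gave mixed results in polysome RNA with rapamycin. Camera did not call those of bile duct (median 0.04, adjusted p = 0.614), granulocytes and mast cells (0.15, adjusted p = 0.107) or megakaryocytes (0.13, adjusted p = 0.126). Of 17 endothelial genes, 4 rose (13 adjusted over the list alone), with a median of 0.38 and Emcn (0.72), Plvap (0.72) and the angiopoietin receptor gene Tek (0.62) in front (adjusted p = 1.38e-07; adjusted p = 0.48 with an estimated correlation). Among 19 macrophage genes Adgre1 rose by 0.67, and it was the only one adjusted over the list alone as well, with a list median of 0.22 (adjusted p = 0.000216; adjusted p = 0.48 with an estimated correlation). Of 21 stellate cell and fibroblast genes, Pdgfrb rose by 0.50 (1 adjusted over the list alone) and the median was 0.25 (adjusted p = 0.00122; adjusted p = 0.48 with an estimated correlation). Of 24 acute phase genes, 2 rose, Il1rn (0.78) and the ceruloplasmin gene Cp (0.70), with 3 adjusted over the list alone and a median of 0.14 (adjusted p = 2.23e-05; adjusted p = 0.48 with an estimated correlation). Of 40 autophagy and lysosome genes, Ulk2 rose by 0.68 (1 adjusted over the list alone) and the median was 0.09 (adjusted p = 0.00347; adjusted p = 0.48 with an estimated correlation). Single arrays moved some of these medians: without DMSO 1 the macrophage median was 0.36 and the autophagy median 0.14, without rapamycin 3 the macrophage median was 0.15, and without DMSO 3 the stellate cell median was 0.14.

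Other lists of the translation machinery moved less and rested on single livers. The mRNAs with a 5′ terminal oligopyrimidine tract outside the ribosomal proteins, such as those of elongation factors, had a median of −0.18 over 22 genes with 0 called one by one by limma among all genes and 7 adjusted over the list alone. Their camera adjusted p was 0.0149 (adjusted p = 0.577 with an estimated correlation), 0.273 without DMSO 2 (median −0.04) and 0.113 without rapamycin 3 (median −0.09). Ribosome biogenesis genes had a median of −0.25 over 43 genes, of which Emg1 fell by 0.84 (0 adjusted over the list alone), with a camera adjusted p of 0.000143 (adjusted p = 0.577 with an estimated correlation) that became 0.0623 without DMSO 2. The fed-liver enzyme list (median 0.18) lost its camera call without DMSO 3 (adjusted p = 0.106). Its pyruvate kinase gene Pklr rose by 0.92 (adjusted p = 0.00837) and passed whichever array was left out. Single genes of rapamycin's pathway changed little, none past the threshold. Mtor changed by −0.09 (adjusted p = 0.525), Rps6 by −0.17 (0.326) and the translation repressor gene Eif4ebp1 by −0.24 ± 0.09 (0.129). Igfbp1, whose product binds insulin-like growth factors, differed by 1.34 ± 0.376 (adjusted p = 0.0554).

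Total RNA of the same livers was compared in the same way. With rapamycin 160 transcript clusters rose and 384 fell, among them 62 and 232 by more than 1.5-fold. Mocos rose by 1.80 ± 0.112 (adjusted p = 1.84e-05), followed by Nr0b2 (1.38), Serpina7 (1.34), Kmo (1.31), Socs2, a brake on growth hormone signalling (1.29), Popdc2 (1.24), Rcan2 (1.15), Mamdc2 (1.06), Ror1 (1.05) and Gpx2 (1.04). The largest falls were those of Kif20a (−2.34 ± 0.408, adjusted p = 0.0199), Cdkn3 (−2.22), Ect2 (−2.20), Ccnb1 (−2.19), Ccnb2 (−2.12), the securin gene Pttg1 (−2.08), Parpbp (−2.07), Cdc20, an activator of the anaphase-promoting complex (−2.05), Trim59 (−1.99) and Cep55 (−1.95). In all 20 the rapamycin livers lay apart from the DMSO livers, as the selection favours. Between the fractions 330 calls were shared, 104 up and 226 down, all in the same direction, where independent lists would share 34.6, and since both fractions came from the same livers this overlap is not independent evidence. Without single arrays the count was 847 (DMSO 1), 10 (DMSO 2), 5 (DMSO 3), 4 (rapamycin 1) and 8 (rapamycin 3), and Mocos and Psat1 passed in every such fit. Cyclic loess scaling moved the share of calls that rose from 29.4% to 40.9%.

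In total RNA 34 of 38 mitosis genes fell (38 adjusted over the list alone), with a median of −1.64 (camera adjusted p = 2.99e-26; adjusted p = 0.41 with an estimated correlation), and 8 of 39 replication genes (22 adjusted over the list alone), with a median of −0.62 (adjusted p = 3.57e-12; adjusted p = 0.414 with an estimated correlation). All 35 proteasome genes were lower, with a median of −0.23, 1 fell among all genes and 0 adjusted over the list alone (adjusted p = 8.69e-07; adjusted p = 0.433 with an estimated correlation). Mitochondrial ribosomal protein mRNAs had a median of −0.22, with 9 that fell (18 adjusted over the list alone; adjusted p = 6.39e-08; adjusted p = 0.433 with an estimated correlation). ATF4 targets had a median of −0.30, with 5 that fell among all genes, and 12 that fell and 1 that rose adjusted over the list alone (adjusted p = 4.52e-05; adjusted p = 0.41 with an estimated correlation). Among initiation factors 3 fell (4 adjusted over the list alone), including Eif4e, the cap-binding protein gene, at −0.56, with a list median of −0.17 (adjusted p = 0.000568; adjusted p = 0.474 with an estimated correlation). Ribosomal protein mRNAs had a median of −0.12, with 0 called by limma among all genes and 0 adjusted over the list alone. That list's camera adjusted p was 0.00151 (adjusted p = 0.632 with an estimated correlation) and became 0.14 without DMSO 2, while the median was −0.19 without DMSO 1. Endothelial genes rose in total RNA as well, 4 of 17 (6 adjusted over the list alone), with a median of 0.31 and Emcn at 0.88 (adjusted p = 3.56e-06; adjusted p = 0.41 with an estimated correlation). Macrophage genes had a median of 0.02 there (adjusted p = 0.566).

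Further marker lists passed camera's threshold in 1 fraction only after hepatectomy, each with a call lost when single arrays were left out. Of 11 lymphocyte genes in polysome RNA Cd74 rose by 0.43 (3 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.0183; adjusted p = 0.48 with an estimated correlation). That call was lost without DMSO 2 (adjusted p = 0.0523) and without rapamycin 3 (adjusted p = 0.21, median 0.08). Of 20 erythroid genes in polysome RNA limma called 0 among all genes and 0 adjusted over the list alone, with a median of 0.20 (adjusted p = 0.00641; adjusted p = 0.48 with an estimated correlation; adjusted p = 0.0589 without rapamycin 3). In total RNA limma called 0 of 17 granulocyte and mast cell genes and 0 of 9 megakaryocyte genes, also 0 and 0 adjusted over each list alone. Their medians were 0.15 and 0.15 (adjusted p = 0.0166 and 0.0236; adjusted p = 0.41 for both with an estimated correlation). The granulocyte call was lost without rapamycin 3 (adjusted p = 0.0788, median 0.10) and the megakaryocyte call without DMSO 1 (adjusted p = 0.0825). Lymphocyte (0.02), erythroid (0.16) and bile duct genes (0.13) were not called in total RNA, at adjusted p of 0.154, 0.151 and 0.151. Stellate cell and fibroblast genes were called there too, with a median of 0.25 (adjusted p = 0.000631; adjusted p = 0.41 with an estimated correlation).

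Camera called further lists in total RNA after hepatectomy. Lower were oxidative phosphorylation (median −0.12, adjusted p = 0.000172), ribosome biogenesis (−0.22, 5.56e-05), heat shock proteins (−0.32, 0.000408) and mTOR components (−0.15, 0.00814). Higher were immediate early (0.30, 0.000495), acute phase (0.08, 0.00733) and autophagy genes (0.09, 0.0126). With an estimated correlation their adjusted p were 0.474, 0.541, 0.41, 0.41, 0.41, 0.596 and 0.41. Fed-liver enzymes were called too (0.26), but not without DMSO 3 (adjusted p = 0.0548) or rapamycin 3 (0.1). Without single arrays the autophagy call was lost (DMSO 2, adjusted p = 0.0596), and the median was −0.14 for ribosome biogenesis and 0.05 for acute phase genes without DMSO 2 and 0.13 for immediate early genes without rapamycin 1. Genes of cholesterol synthesis were called as higher in both fractions, with medians of 0.21 in polysome and 0.22 in total RNA (adjusted p = 0.0111 and 0.0166; adjusted p = 0.599 and 0.632 with an estimated correlation). Those calls were lost without DMSO 3 (adjusted p = 0.344 and 0.235, medians 0.10 and 0.13) and without rapamycin 3 (adjusted p = 0.304 and 0.556, medians 0.09 and 0.10), while the medians were 0.34 and 0.36 without DMSO 1, and that of total RNA was 0.34 without rapamycin 2. Initiation factors in polysome RNA had a median of −0.14 (adjusted p = 0.0261; adjusted p = 0.577 with an estimated correlation), and the call was lost without DMSO 2 (adjusted p = 0.294, median −0.09), rapamycin 2 (adjusted p = 0.0524) and rapamycin 3 (adjusted p = 0.17).

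**Figure D2:**
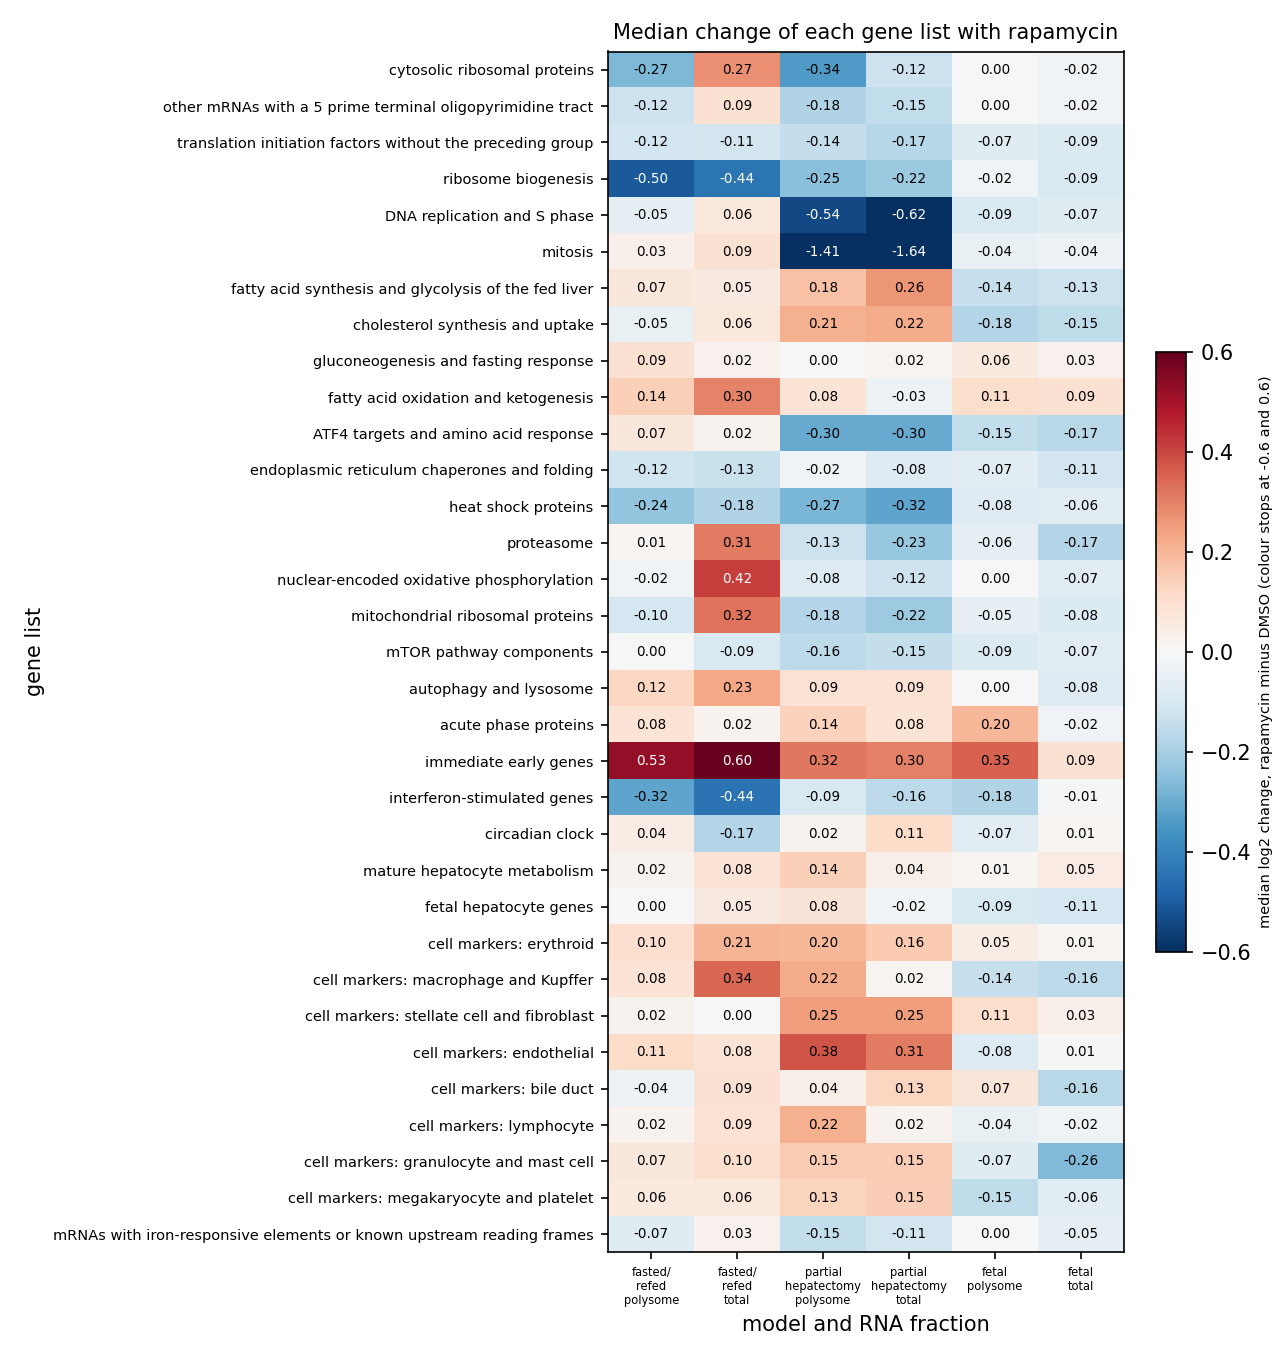
Median log2 change with rapamycin (rapamycin minus DMSO, colour and printed value; the colour scale ends at ±0.6) of 33 gene lists (rows) in polysome and total RNA of the 3 models (columns; n = 3 livers per group in adults, n = 4 in fetuses). The mitosis list lies at −1.41 and −1.64 after partial hepatectomy, and the ribosomal protein list at −0.27 and −0.34 in polysome RNA of the fasted/refed and hepatectomy models.

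In the fasted/refed model the question was how rapamycin changes polysomal mRNA during growth without proliferation, as the fasted liver is refed. No single gene passed, while ribosomal protein, ribosome biogenesis and heat shock mRNAs were lower on polysomes and immediate early and autophagy mRNAs were higher. These were camera calls of whole lists, and with an estimated correlation their adjusted p were 0.578, 0.616, 0.359, 0.578 and 0.571. Ribosome biogenesis genes had a median log2 change of −0.50, which became −0.20 without DMSO 3, and all 43 were lower, led by Nop56, a core protein of small nucleolar ribonucleoproteins (−0.98). The gene with the smallest p was Cry1, a repressor of the circadian clock, at −1.24 ± 0.162 (SE, n = 3 per group; adjusted p = 0.0875). Pck1, the rate-controlling enzyme of gluconeogenesis, stood at 9.74 ± 0.217 (SD) with DMSO and 11.83 ± 0.749 with rapamycin, a log2 difference of 2.09 ± 0.358 (SE; adjusted p = 0.239).

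Limma called 0 transcript clusters in fasted/refed polysome RNA, with 526 at an unadjusted p under 0.05. Next to Cry1 and Pck1 the smallest p belonged to Akr7a3 (0.89) and Ces1c (0.50) among higher genes, and Dph5 (−0.74) and Lrrc59 (−0.59) among lower ones. With the list's 0 calls among all genes, ribosomal protein mRNAs had a median of −0.27, 66 of 68 lower and 0 passed adjusted over the list alone (camera adjusted p = 2.44e-22; adjusted p = 0.578 with an estimated correlation). For ribosome biogenesis the camera adjusted p was 6.23e-16, with 1 gene, Nop56, adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). All 18 heat shock genes were lower, with a median of −0.24, Chordc1 at −0.72 and Hsph1 at −0.45, and 3 passed adjusted over the list alone (adjusted p = 3.62e-09; adjusted p = 0.359 with an estimated correlation). Of 25 immediate early genes, 23 were higher, with a median of 0.53 and Egr1 (1.60), Junb (1.33) and Myc (1.04) in front, and Egr1 passed adjusted over the list alone (adjusted p = 1.25e-08; adjusted p = 0.578 with an estimated correlation). Without rapamycin 2 that median was 0.29. Autophagy and lysosome genes had a median of 0.12 with Ulk1, the kinase that starts autophagy, at 0.76, and 0 passed adjusted over the list alone (adjusted p = 0.000916; adjusted p = 0.571 with an estimated correlation). The autophagy median was 0.08 without DMSO 3. Mitochondrial ribosomal protein mRNAs had a median of −0.10, with Mrps10 at −0.56 and 0 adjusted over the list alone (adjusted p = 0.00143; adjusted p = 0.842 with an estimated correlation). Of the genes of this pathway fixed for reporting, Igfbp1 differed by 2.05 ± 0.789 (adjusted p = 0.957) and Rps6 by −0.34 ± 0.131 (adjusted p = 0.957).

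In fasted/refed total RNA limma also called 0 transcript clusters, but 1832 had an unadjusted p under 0.05, and 1756 passed (1309 up, 447 down) when the total array of DMSO 2 was left out. The smallest p belonged to Akr7a3 (1.07, adjusted p = 0.0785), Gabarapl1, which encodes a protein of the autophagosome membrane (1.11, adjusted p = 0.117), Lztfl1 (0.94), Ints2 (−1.33), Cry1 (−0.95) and Ogfod1 (−1.22). Nuclear-encoded genes of oxidative phosphorylation were higher, 65 of 68, with a median of 0.42 and Atp5po at 0.82 (camera adjusted p = 7.18e-15; adjusted p = 0.714 with an estimated correlation). Ribosomal protein mRNAs were higher too, 66 of 68, with a median of 0.27 and Rps10 at 0.895 (adjusted p = 3.92e-08; adjusted p = 0.714 with an estimated correlation). Proteasome genes had a median of 0.31 (adjusted p = 2.43e-05) and ribosome biogenesis genes one of −0.44 (adjusted p = 2.84e-09), each with an adjusted p of 0.714 with an estimated correlation. None of these 4 lists held a gene called among all genes, and each rested in part on single arrays. The oxidative phosphorylation median was 0.26 and the ribosome biogenesis median −0.15 without DMSO 3, the ribosomal protein median was 0.16 without rapamycin 2, and the proteasome median was 0.16 without DMSO 1 and 0.20 without rapamycin 2. Among total RNA arrays DMSO 1 and DMSO 3 lay apart on the first principal component, at 38.7 and 47.2 against −1.66 to 17.5, and in the ribosomal protein mean DMSO 2 (11.99) lay among the rapamycin livers (11.77 to 12.22). Autophagy and lysosome genes had a median of 0.23 with 6 adjusted over the list alone (adjusted p = 2.29e-05; adjusted p = 0.714 with an estimated correlation). Immediate early genes had a median of 0.60 with 7 adjusted over the list alone (adjusted p = 2.12e-05; adjusted p = 0.714 with an estimated correlation), and without rapamycin 2 that median was 0.30. The livers DMSO 3 and rapamycin 2 stood apart from the other 4 in both fractions: Cyp7a1, the rate-limiting enzyme of bile acid synthesis, measured 9.13 and 10.35 in their polysome RNA against 12.60 to 12.77, and the mean of the acute phase list 13.05 and 13.09 against 12.07 to 12.54. Without both livers limma called 0 transcript clusters in either fraction.

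In fetal liver the question was whether rapamycin acts on hepatic translation before birth. Neither fraction held a gene past the threshold, and the ribosomal protein list, lower on polysomes in both adult models, showed 34 genes higher and 34 lower with a median of −0.002 (camera adjusted p = 0.161). The acute phase and immediate early lists were called higher in polysome RNA by camera, with no member called and an adjusted p of 0.242 for each with an estimated correlation. Without the liver rapamycin 2 their medians, 0.20 and 0.35, became 0.12 and 0.07. The gene with the smallest p in polysome RNA was Camk1, a calmodulin-dependent kinase, at −0.60 ± 0.105 (SE, n = 4 per group; adjusted p = 0.327), and in total RNA the carboxylesterase gene Ces2g at 0.77 ± 0.139 (adjusted p = 0.523).

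Limma called 0 transcript clusters in fetal polysome RNA and 0 in total RNA, with 247 and 199 at an unadjusted p under 0.05, and 0 in each when the replicate number, which paired DMSO with rapamycin livers, was a block. In polysome RNA the next smallest p belonged to Ces2g (0.51), Maff (0.53) and Pla2g5 (0.40) among higher genes, and to Slc9a9 (−0.45) and C13h2orf76 (−0.46) among lower ones. In total RNA they belonged to Trim69 (0.81), Pyroxd2 (0.60), Ceacam4 (−0.79), Defa11 (−0.74) and Stfa3 (−0.63). Of 24 acute phase genes, 23 were higher on polysomes, with a median of 0.20, Steap4 at 1.15 and Il1rn at 0.83 (camera adjusted p = 4.31e-12; adjusted p = 0.242 with an estimated correlation). Of 25 immediate early genes, 22 were higher, with a median of 0.35 and Gadd45b at 1.04 (adjusted p = 3.29e-11; adjusted p = 0.242 with an estimated correlation). The liver rapamycin 2 stood highest of its group in the means of both lists, at 12.67 against 11.77 to 12.12 and at 10.08 against 9.04 to 9.21. The acute phase median was 0.12 without it and 0.12 without DMSO 1, and the immediate early median was 0.07 without it. Interferon-stimulated genes had a median of −0.18 (adjusted p = 0.00182; adjusted p = 0.852 with an estimated correlation). In total RNA granulocyte markers had a median of −0.26 with Ngp at −1.18 and S100a8 at −0.57 (adjusted p = 0.000261; adjusted p = 0.325 with an estimated correlation), and macrophage markers one of −0.16 with Cd5l at −1.02 (adjusted p = 0.00058; adjusted p = 0.817 with an estimated correlation). ATF4 targets had a median of −0.17 in total RNA (adjusted p = 0.000261; adjusted p = 0.817 with an estimated correlation). Without rapamycin 1 the granulocyte median was −0.16 and the ATF4 median −0.06. In all 6 lists limma called 0 genes, and 0 passed adjusted over the list alone. With the block, camera also called the replication list (median −0.09, adjusted p = 0.0284 in polysome RNA; −0.07, 0.0352 in total RNA), the mTOR component list (−0.09, 0.0434) and the macrophage list (−0.14, 0.0417) in polysome RNA, and the autophagy list (−0.08, 0.0444) in total RNA. With an estimated correlation and the block their adjusted p were 0.862, 0.722, 0.443, 0.747 and 0.634.

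Whether an mRNA moved on polysomes beyond its change in total RNA was tested as the difference of the rapamycin effects in the 2 fractions. Camera called the ribosomal protein list lower on polysomes relative to total RNA in both adult models. No single gene passed, and with an estimated correlation the adjusted p were 0.981 in the fasted/refed model and 0.925 after hepatectomy. After hepatectomy the median difference was −0.20 and 65 of 68 were lower, with Rps15a and Rps12 at −0.64. The median in the fasted/refed model was −0.58 and all 68 were lower, with Rplp1 at −0.97. Fetal livers showed a median of 0.02, with 40 higher and 28 lower.

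Limma called 0 single transcript clusters in these tests, with 266, 158 and 45 at an unadjusted p under 0.05 in the fasted/refed, hepatectomy and fetal models. The camera adjusted p of the ribosomal protein list was 1.56e-38 in the fasted/refed model (adjusted p = 0.981 with an estimated correlation) and 7.72e-31 after hepatectomy (adjusted p = 0.925 with an estimated correlation). With the liver as a block, which used the pairing of the fractions, 57 of 68 passed adjusted over the list alone in the fasted/refed model and 30 of 68 after hepatectomy, where 0 had passed in either without it. Other lists moved the same way in the fasted/refed model: oxidative phosphorylation by a median of −0.44 (adjusted p = 2.04e-20), mitochondrial ribosomal proteins by −0.41 (adjusted p = 5.79e-18) and the proteasome by −0.30 (adjusted p = 3.65e-05), each with an adjusted p = 0.981 with an estimated correlation. The oxidative phosphorylation median was −0.29 without DMSO 3, and the proteasome median −0.48 without DMSO 2 and −0.20 without rapamycin 2. After hepatectomy all 19 macrophage genes were higher on polysomes relative to total RNA, with a median of 0.22 and Lyz2 at 0.45 (adjusted p = 4.09e-07; adjusted p = 0.925 with an estimated correlation), and without DMSO 3 that median was 0.13. With the liver block mitosis genes, with a median of 0.29, had an adjusted p of 1.34e-09 (0.051 without it; adjusted p = 0.725 with an estimated correlation and the block), and replication genes, with a median of 0.12, one of 0.000949 (0.093 without it; adjusted p = 0.725 with an estimated correlation and the block). In fetal livers acute phase genes were higher on polysomes relative to total RNA by a median of 0.27 (adjusted p = 6.21e-10; adjusted p = 0.563 with an estimated correlation), which became 0.10 without rapamycin 2. Polysome minus total, the acute phase mean was 0.859 in rapamycin 2 and −0.168 to −0.038 in the other 3 rapamycin livers. The single genes with the smallest p were Notch4 (0.47) and Rpl37a (−0.73) in the fasted/refed model, Bag1 (0.53) and Osgep (−0.54) after hepatectomy, and Zbtb24 (0.49) and Polm (−0.46) in fetuses, none past the threshold.

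Because camera treats genes as nearly independent, the mean of the ribosomal protein list was also taken per liver and compared by an exact permutation test over livers, chosen after seeing the data. In polysome RNA it was 12.48 ± 0.0914 (SD, n = 3) with DMSO and 12.20 ± 0.167 with rapamycin in the fasted/refed model, and 12.54 ± 0.124 and 12.18 ± 0.0739 after hepatectomy. In each model the livers did not overlap, with an exact p of 0.1, the smallest that 3 against 3 livers allow. Over both adult models the exact 2-sided p was 0.005, the smallest of the 400 splits within models, for a difference of −0.32 (adjusted p = 0.033 over 33 lists, with 3 of 3 rapamycin livers below 3 of 3 DMSO livers in each model). The heat shock list (−0.26), the mitochondrial ribosomal protein list (−0.15), the autophagy list (0.12) and the endothelial list (0.26) reached the same adjusted p of 0.033 by the exact test in polysome RNA. In total RNA the ribosomal protein list differed by 0.27 in the fasted/refed model (exact p = 0.2) and by −0.12 after hepatectomy (exact p = 0.4). Polysome minus total, the mean differed by −0.545 in the fasted/refed model and by −0.242 after hepatectomy (exact p = 0.005 over both, adjusted p = 0.165), and in fetuses the difference was 0.02 (exact p = 0.943; 0.875 by exact sign flips within the pairs of equal number).

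**Figure D3:**
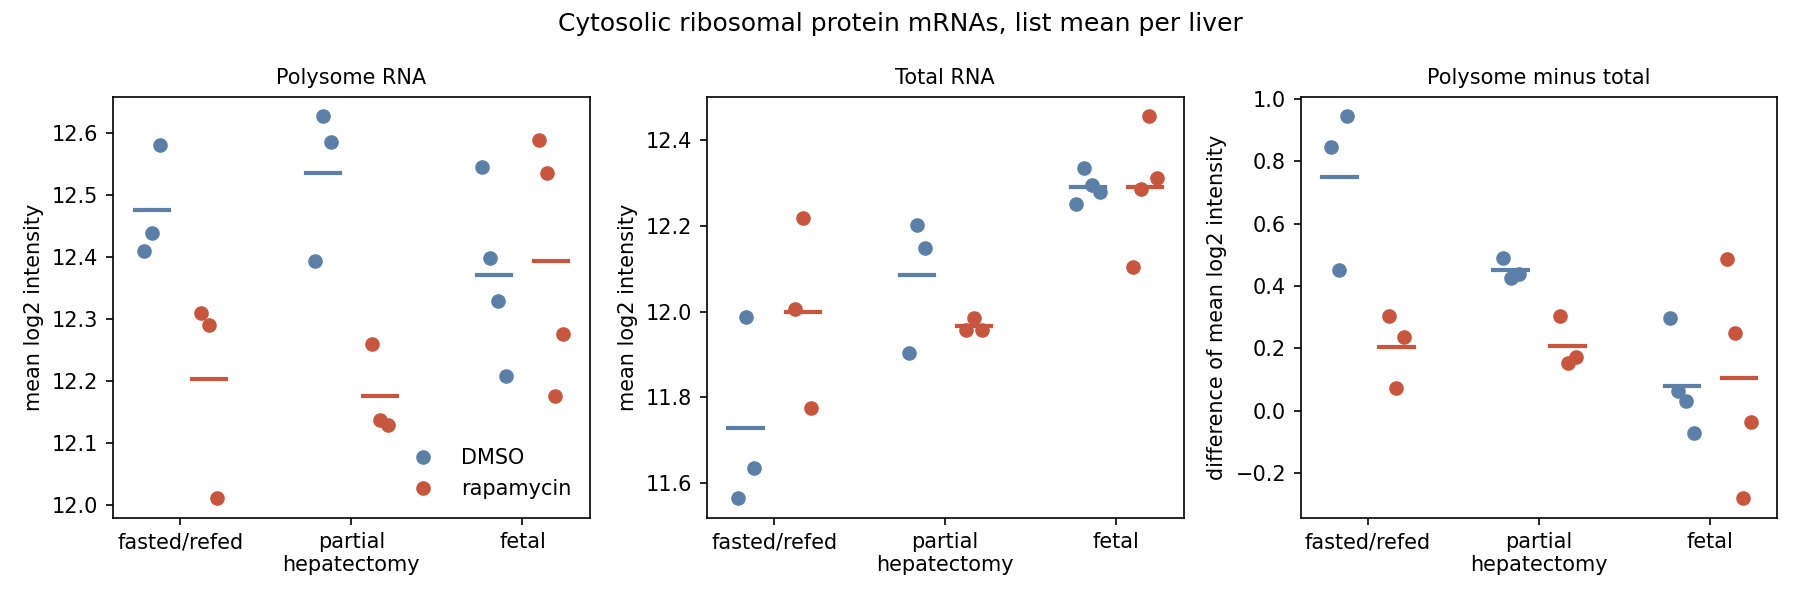
Mean log2 intensity of 68 ribosomal protein mRNAs per liver (y axis) in polysome RNA, in total RNA, and polysome minus total, for DMSO and rapamycin livers of the 3 models (x axis). Points are livers (n = 3 per adult group, n = 4 per fetal group) and lines are group means; in polysome RNA the means are 12.48 and 12.20 in the fasted/refed model and 12.54 and 12.18 after hepatectomy.

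The next comparison asked which genes responded to rapamycin differently in the 3 models, by a test of that difference itself. The effects on Psat1 and Phgdh, enzymes of serine synthesis, differed between the models, while in the fasted/refed model alone neither passed. Time from injection to harvest was a few hours in the fasted/refed model and about a day in the others. The dose differed between adults and fetuses as well. Model, time and dose therefore cannot be told apart in this comparison. In polysome RNA Psat1 differed by 1.10 in the fasted/refed model, −1.92 after hepatectomy and −0.54 in fetuses (adjusted p = 7.4e-06), and Phgdh by 0.71, −1.52 and −0.25 (adjusted p = 0.00604). Birc5 differed by 0.01, −1.78 and 0.04 (adjusted p = 0.00147) and the centrosomal gene Cep128 by 0.07, −1.35 and −0.10 (adjusted p = 0.0363). These were the 4 transcript clusters that passed limma's moderated F-test in polysome RNA. In fasted/refed livers Birc5 (6.71 with DMSO) and Cep128 (6.43) lay near or under the filter of 6.7, so a fall could hardly have shown there and their effects near 0 are no evidence that the drug left them unchanged. In fetal DMSO livers they stood at 9.23 and 8.59, so this limit does not apply to the fetal values.

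In total RNA 46 passed, led by Psat1 (1.39, −1.86 and −0.47; adjusted p = 1.25e-06), Phgdh (0.95, −1.52 and −0.06; adjusted p = 0.00122), Stmn1, a destabiliser of microtubules (1.00, −1.30 and −0.07; adjusted p = 0.00777), Birc5 (0.02, −1.56 and 0.01; adjusted p = 0.00777) and Ror1 (−0.58, 1.05 and 0.43; adjusted p = 0.00777). Eif4ebp1, the repressor of cap-dependent translation, differed by 0.84, −0.32 and −0.19 (adjusted p = 0.016). All 4 genes of the polysome test and 36 of the 46 of the total RNA test had also passed after hepatectomy, where 4 and 35 of them fell, and 1 and 10 belonged to the mitosis list. Of the 46, 18 lay under the filter in fasted/refed DMSO livers and 0 in fetal ones, Birc5 at 6.66 and 8.93, while Psat1 (9.21), Phgdh (8.99) and Stmn1 (8.10) lay above it in fasted/refed livers. On simulated data 22% of the calls of the polysome F-test and 20.5% of those of the total RNA test were false, against a nominal 5%. With the fetal replicate number as a block 64 and 360 transcript clusters passed. The polysome count was 13 without fetal DMSO 2, 17 without hepatectomy DMSO 1, 2 without hepatectomy DMSO 2 and 41 without hepatectomy rapamycin 2, and Cep128 lost its call in 12 of the 20 such fits and Phgdh in 1. The total RNA count was 1332 without fasted/refed DMSO 2 and 133 without hepatectomy rapamycin 2. It was 13 and 10 without fasted/refed DMSO 1 and DMSO 3, 19, 11 and 18 without fasted/refed rapamycin 1, 2 and 3, and 4, 4, 2 and 3 without hepatectomy DMSO 2, DMSO 3, rapamycin 1 and rapamycin 3. It was 18 and 15 without fetal DMSO 3 and DMSO 4, and 29, 18 and 71 without fetal rapamycin 1, 2 and 3.

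Polysome RNA was set against total RNA in DMSO livers to describe which mRNAs were relatively rich on polysomes without the drug. In all 3 models mRNAs of the mitochondrial ribosome and of oxidative phosphorylation were richer on polysomes, and mRNAs of stellate cells and fibroblasts, of endothelial cells and of chaperones of the endoplasmic reticulum were poorer, by camera's calls of these lists. With an estimated correlation none of these calls held, at adjusted p from 0.0645 to 0.803. Med21, a Mediator subunit, led in every model at 2.64, 2.61 and 2.41 (fasted/refed, hepatectomy, fetal). Atp5mg, a subunit of ATP synthase, stood at 2.54, 2.20 and 1.81. Rpph1, the RNA of ribonuclease P, which is not translated, stood at −2.00 in the fasted/refed and −2.11 in the hepatectomy model.

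In the fasted/refed model 2121 transcript clusters were higher and 558 lower on polysomes, after hepatectomy 3131 and 1627, and in fetuses 880 and 693. With the liver as a block 4615 passed in the fasted/refed model and 3044 in fetuses. The other largest differences in the fasted/refed model were H4c14 (2.56), Psmg4 (2.43) and the acyl-CoA-binding protein gene Dbi (2.41), and Sptbn1 (−1.66), Dmbt1 (−1.47), Ccdc107 (−1.47) and Mlxipl, a glucose-responsive transcription factor (−1.45). After hepatectomy they were Psmg4 (2.36), Tmem256 (2.18), Crip1 (2.07), Col14a1 (−1.89), Sptbn1 (−1.72), Arsk (−1.58) and Hgf, the hepatocyte growth factor (−1.50). In fetuses they were Tmem256 (2.22), Timm13 (1.73), Crip1 (1.67), Ccdc107 (−1.91), Itm2a (−1.79), Asah1 (−1.74), Aspn (−1.68) and Mmp8 (−1.67). Mitochondrial ribosomal protein mRNAs were higher on polysomes in 66 of 70 cases (68 adjusted over the list alone; median 1.00), 63 of 70 (64; 0.76) and 27 of 70 with 1 lower (31 and 1; 0.42). The camera adjusted p were 1.81e-23, 1.38e-17 and 1.28e-08, and with an estimated correlation the adjusted p were 0.714, 0.516 and 0.622. Ribosomal protein mRNAs were higher in 53 of 68 in the fasted/refed model (57 adjusted over the list alone), led by Fau (1.61) and Rps14 (1.49), and in 48 after hepatectomy with 2 lower (51 and 2), with medians of 0.73 and 0.39 (adjusted p = 1.25e-16 and 2.41e-07). With an estimated correlation their adjusted p were 0.714 and 0.786. In fetuses 7 were higher and 9 lower with a median of 0.08 (adjusted p = 0.999). Stellate cell and fibroblast mRNAs were lower on polysomes in 8, 14 and 13 of 21, with medians of −0.39, −0.58 and −0.57 and Pdgfrb at −1.15, −1.46 and −1.22 (adjusted p = 7.84e-07, 6.42e-07 and 6.4e-10). With an estimated correlation their adjusted p were 0.125, 0.513 and 0.0645. Chaperones and folding factors of the endoplasmic reticulum had medians of −0.27, −0.27 and −0.47, with Hyou1 at −1.04 and −1.18 in the adult models and Pdia4 at −0.86 in fetuses.

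The 3 further lists named above gave these tests. Of 24 chaperone and folding genes, 9 were lower and 1 higher in the fasted/refed model (12 and 2 adjusted over the list alone), 11 and 3 after hepatectomy (12 and 3) and 13 and 0 in fetuses (18 and 0). Their camera adjusted p were 0.000472, 0.00108 and 2.64e-10, and with an estimated correlation the adjusted p were 0.714, 0.803 and 0.189. Of 68 oxidative phosphorylation genes 57, 55 and 23 were higher and 0, 3 and 0 lower (60, 56 and 31 higher and 0, 3 and 1 lower adjusted over the list alone), with medians of 0.96, 0.66 and 0.33. The adjusted p of that list were 3.95e-19, 7.75e-14 and 5.64e-08, and with an estimated correlation 0.714, 0.513 and 0.622. Of 17 endothelial genes 7, 11 and 5 were lower and 1, 1 and 0 higher (10, 11 and 6 lower and 1, 1 and 0 higher adjusted over the list alone), with medians of −0.38, −0.41 and −0.32. Their adjusted p were 0.000313, 0.000741 and 0.00249, and with an estimated correlation 0.0866, 0.778 and 0.622.

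The scaling set part of these counts. Over all transcript clusters the median of polysome minus total in the fasted/refed model was 0.103 on the log2 scale and became −0.0358 under cyclic loess, while no list that camera called changed the sign of its median. Loess moved the share of calls higher on polysomes from 79.2% to 56% in the fasted/refed model, from 65.8% to 50% after hepatectomy and from 55.9% to 43.1% in fetuses. Without single livers the fasted/refed count was 924 (DMSO 1) and 1423 (DMSO 3), that after hepatectomy 2990 (DMSO 3), and the fetal count 522, 697, 839 and 687 (DMSO 1, 2, 3 and 4).

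The DMSO livers of the models were compared in total RNA to describe the tissue on which rapamycin acted. Against fasted/refed livers, livers 24 h after hepatectomy were rich in cell cycle mRNA: all 38 mitosis genes and all 39 replication genes were higher, with median log2 differences of 3.96 and 2.07. Rrm2, a subunit of ribonucleotide reductase, was higher by 6.57 ± 0.378 (SE, n = 3 per group), and Ect2 (5.69), Top2a (5.69), Nusap1 (5.46) and Pbk (5.44) followed. Inmt (−4.50), Sult1c2 (−3.51), Igfbp2 (−3.29), the cytochrome P450 gene Cyp2b1 (−2.92) and Aox1 (−2.65) were lowest. The camera adjusted p was 4.93e-73 for the mitosis and 6.9e-47 for the replication list (0.0184 and 0.03 with an estimated correlation). Each kept its count adjusted over the list alone. Of 22 genes of cholesterol synthesis 13 were higher (16 adjusted over the list alone), with Idi1 at 2.37 (adjusted p = 2.5e-08, and 0.765 with an estimated correlation).

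Fetal livers differed from fasted/refed livers in their blood-forming cells and in hepatocyte maturity. All 20 erythroid, 17 granulocyte and mast cell and 9 megakaryocyte markers were higher, with medians of 4.48, 3.38 and 2.73. The granulocyte mean was 6.2 to 6.8 in fasted/refed DMSO livers, near the filter, so the median of 3.38 is uncertain. Ahsp, which stabilises alpha globin, was higher by 7.24, Car1 by 6.85, Bex4 by 6.67, the fetal albumin homologue Afp by 6.64 and the embryonic globin gene Hbe1 by 6.61. Cyp2c13 (−7.64), Tdo2, which degrades tryptophan (−7.38), Car3 (−6.95), Slco1a4 (−6.85) and Cyp2c6v1 (−6.81) were lowest. The adjusted p of these 3 marker lists were 6.83e-19, 8.27e-16 and 7.79e-09, and with an estimated correlation 0.0723, 0.00119 and 0.0273. Of 18 fetal hepatocyte genes 15 were higher and 2 lower (adjusted p = 4.96e-10, and 0.00174 with an estimated correlation). Of 35 genes of mature hepatocyte metabolism 3 were higher and 18 lower (adjusted p = 2.61e-07 and 0.439). All these lists kept their counts adjusted over the list alone.

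Between hepatectomy and fasted/refed livers 1352 transcript clusters were higher and 546 lower, and between fetal and fasted/refed livers 3054 and 2060, while on simulated data 12.5% and 25.3% of such calls were false. Loess moved the share of higher calls from 71.2% to 59.8% after hepatectomy and from 59.7% to 49.9% in fetal livers. The hepatectomy count was 1220, 2890 and 1257 without fasted/refed DMSO 1, 2 and 3, and 1264 and 1119 without hepatectomy DMSO 2 and DMSO 3. Model, age, surgery and any array batch went together in these comparisons and cannot be told apart.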

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

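The tests of the ribosomal protein mRNAs and of the 2 divergent fasted/refed livers, and the splits that keep to fetal pairs or to livers, were chosen only after the results were seen.

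Fetal livers were searched for single samples far from the others of their group, by the gap to the nearest sample relative to the range of the 4. Of 124 such searches over 16 list means and 15 genes in 4 groups, 6 passed the critical value of Dixon's test, where chance gives 1 in 20, or 6.2. In polysome RNA of rapamycin 2 the immediate early list stood at 10.08 (others 9.037 to 9.213) and the macrophage list at 10.02 (others 9.609 to 9.652). In polysome RNA of DMSO 2 the ATF4 list stood at 10.8 (others 10.57 to 10.6). In total RNA of rapamycin 1 the proteasome list stood at 10.3 (others 10.79 to 10.84). In total RNA of rapamycin 2 Eef2 stood at 13.17 (others 13.4 to 13.41) and Ccnb1 at 10.92 (others 10.28 to 10.39).

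The effect of rapamycin differed between the models, by the test of that difference, for 4 transcript clusters in polysome RNA and 46 in total RNA. Model, dose and time from injection to harvest went together in this test. In polysome RNA the adjusted p of limma's F-test was 7.4e-06 for Psat1, 0.00147 for Birc5, 0.00604 for Phgdh and 0.0363 for Cep128. In total RNA it was 1.25e-06 for Psat1, 0.00122 for Phgdh, 0.00777 for each of Stmn1, Birc5 and Ror1, 0.00891 for Cdkn3, 0.00894 for Pttg1, 0.0119 for Nt5dc2, 0.016 for Eif4ebp1 and 0.018 for Cep128. In fasted/refed DMSO livers 1 of the 4 and 18 of the 46 lay under the filter of 6.7, where a fall may not show, so for these that model says little. Chance could not be excluded for the numbers of calls with the livers split freely: of 100 splits of the livers within models, 18 gave at least 4 calls in polysome RNA (highest other 539) and 17 gave at least 46 in total RNA (highest other 2673). Those highest counts, many times the real ones, point to structure among the samples other than treatment. Of 100 splits that part all 4 fetal pairs of equal number, as the real one does, 10 gave at least 4 calls in polysome RNA (highest other 15) and 3 gave at least 46 in total RNA (highest other 221). The share was under 0.05 only for total RNA in these later-chosen splits, so chance was excluded for neither count.

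Transcript clusters without a gene name, which the named comparisons did not use, also changed after hepatectomy. With all rows of the table tested by limma and adjusted together, 158 unnamed ones passed in polysome RNA (43 up, 115 down) and 123 in total RNA (35 up, 88 down), of 7874 unnamed ones among 20178.

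For the comparisons of rapamycin with DMSO in adults, 3 against 3 livers make 10 splits, too few for a share under 0.05. In polysome RNA 10 of 10 splits of the fasted/refed livers gave at least the real count of 0 (highest other 2), and after hepatectomy 1 of 10 gave at least the real 690 (highest other 1). In total RNA the same counts were 10 of 10 for the real 0 (highest other 1) and 1 of 10 for the real 544 (highest other 1). For the difference between fractions 10 of 10 splits gave at least the real 0 in each adult model (highest other 0). For polysome against total RNA 1 of 10 splits gave at least the real 2679 in the fasted/refed model (highest other 0) and 1 of 10 the real 4758 after hepatectomy (highest other 0). For hepatectomy against fasted/refed livers it was 1 of 10 for the real 1898 (highest other 394).

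Fetal livers make 35 splits. All 35 gave at least the real 0 for rapamycin in polysome RNA (highest other 3719), in total RNA (highest other 4373) and for the difference between fractions (highest other 174). The split with the highest count put replicates 1 and 2 of both treatments against 3 and 4, which points to a structure of the samples that the replicate numbers follow. The 8 splits that part all 4 pairs of equal number, as the real one does, gave at most 0, and the fit with the number as a block gave 0. For polysome against total RNA in fetal DMSO livers 1 of 35 splits gave at least the real 1573 (highest other 970), but these exchange arrays between livers. Exchange of the fractions within the 4 livers makes 8 splits, too few for a share under 0.05 (highest other 0). Chance was excluded for fetal against fasted/refed livers (1 of 35, real 5114, highest other 3677).

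Ribosomal protein mRNAs were lower on polysomes, relative to total RNA, in rapamycin livers of both adult models, and 2 technical explanations were tested. A change of the total RNA arrays alone would leave the polysome arrays without a difference, yet the polysome list mean alone separated the treatments (exact permutation p = 0.005 over both models, the smallest possible). Uneven total RNA arrays that shift other well-translated mRNAs alike would move the oxidative phosphorylation list at least 0.5 times as far, by −0.121 after hepatectomy, where it moved by 0.0387 ± 0.0486 (SE), which argues against it there. That list moved in the fasted/refed model by −0.432 ± 0.2 against −0.545 for ribosomal proteins, so this explanation stays open for the size of the difference in that model. That rapamycin lowers the share of these mRNAs on polysomes after hepatectomy is a hypothesis that stays open beside it, found and tested on the same data.

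The fasted/refed livers DMSO 3 and rapamycin 2 stood apart from the other 4, and no biological explanation was tested. A fault of single arrays would leave the other fraction of these livers unaffected, but the deviations of the polysome and total arrays correlated at 0.67 or more. An exchange of their labels was read from Pck1 first and then, after both values had been seen, from a score over genes called after hepatectomy. Pck1 in polysome RNA of rapamycin 2 was 12.31, near the other rapamycin livers (12.21 and 10.96), and that of DMSO 3 was 9.673, near the other DMSO livers (9.564 and 9.982). The score was 1.251 in rapamycin 2 (other rapamycin livers 1.078 and 1.146) and 0.732 in DMSO 3 (other DMSO livers 0.807 and 0.819), which argues against an exchange. Pck1 was among the genes with the smallest p under these labels, so it adds little. Igfbp1 in polysome RNA of DMSO 3 was 11.12, nearer to rapamycin 1 and 3 (12 and 10.78) than to DMSO 1 and 2 (9.93 and 8.89). So were Myc and Psat1 there, but not Cry1, nor Psat1 in total RNA. In rapamycin 2 Igfbp1 (13.29), Myc and Psat1 lay with or beyond rapamycin 1 and 3. What set these livers apart stays unexplained.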

How the results depend on the processing

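The tests with the liver as a random block, 1 weight per model, a fetal-only block, loess scaling for the lists or without both divergent fasted/refed livers were chosen only after the results were seen. Counts are of transcript clusters past an adjusted p of 0.05 in limma. Where a count moved the cause was not tested, except that fits of fewer arrays have fewer degrees of freedom. For rapamycin against DMSO, a fit of only the 2 groups holds each liver once, while the main fit holds it in both fractions.

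After hepatectomy the polysome count of 690 was 482 to 994 with no filter, the stricter filter, all rows, loess, no trend, quality weights or the liver as a random block. It was 193 with all 40 arrays, 146 with only the 2 groups, and 57 to 1687 with 1 array left out. The total RNA count of 544 was 414 to 770 under the same settings except quality weights (1811), 217 with all 40 arrays, 14 with only the 2 groups and 4 to 847 with 1 array left out. In the fasted/refed model the polysome count of 0 became 71 with quality weights, 5 with all 40 arrays, 1 with the liver as a random block and 0 to 1 with 1 array left out. The total RNA count of 0 became 2 with quality weights, 349 with all 40 arrays and 0 to 1756 with 1 array left out. Without both divergent livers it stayed at 0. Fetal counts and those of the difference between fractions were 0 under every alternative run, 0 to 0 with 1 array left out.

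Adult replicate numbers did not pair DMSO with rapamycin: 0 of 6 fasted/refed and 3 of 6 hepatectomy pairs matched their own number best, against 7 of 8 in fetuses. With that number as a block the counts were 1481 (polysome) and 1246 (total) after hepatectomy, and 2 (polysome) in the fasted/refed model. The F-test counts with the block were 209 (polysome) and 847 (total), and 64 and 360 with a fetal-only block. With the liver as a block polysome against total RNA gave 4615 in the fasted/refed model, 6629 after hepatectomy and 3044 in fetuses. Beside the list calls given with the results, the block added immediate early genes (difference between fractions after hepatectomy, 0.028), oxidative phosphorylation (hepatectomy polysome RNA, 0.0473) and cholesterol synthesis and macrophage genes (polysome against total after hepatectomy, 0.0414 and 0.0474). It ended the calls of mTOR components (0.0615) and autophagy (0.065) in fetal polysome against total RNA, and changed no other list call.

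The polysome F-test count of 4 was 162 with quality weights, 8 with 1 weight per model and 2 to 41 with 1 array left out. The total RNA count of 46 was 15 with no filter, 18 with all rows, 18 with loess, 533 with quality weights, 2 with the fraction's 20 arrays alone, 2 without the divergent livers and 2 to 1332 with 1 array left out. Polysome against total RNA in the fasted/refed model (2679) gave 4378 with all rows, 1169 with only the 2 groups and 924 to 2867 with 1 liver left out. After hepatectomy (4758) it gave 7142 with all rows, 2840 with all 40 arrays and 2990 to 4437, and in fetuses (1573) 2651 with quality weights and 522 to 839. Hepatectomy against fasted/refed livers (1898) gave 2918 with quality weights, 620 with only the 2 groups and 1119 to 2890. Fetal against fasted/refed livers (5114) gave 7750 with all rows, 3402 with only the 2 groups and 4482 to 5191.

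Of the 161 list calls, 143 stayed past the threshold under loess (18 did not) and 154 without the filter (7 did not), and 134 did with the block where it was run (2 did not). With 1 replicate left out 814 tests of these lists stayed past it, 121 did not and 1 reversed. That was the oxidative phosphorylation list: in fetal total RNA its median was −0.0685 (adjusted p = 0.0117), 0.0676 without rapamycin 1 (adjusted p = 0.0396) and −0.158 to 0.0676 over the 8 arrays left out. Of the calls of named genes 340 stayed past the threshold under loess (12 did not), and with 1 replicate left out 1495 tests of them did and 506 did not. The mean of the ribosomal protein list, polysome minus total, differed by −0.421 to −0.693 in the fasted/refed model, −0.214 to −0.29 after hepatectomy and −0.103 to 0.153 in fetuses without the filter, under loess and with 1 liver left out. Dim transcript clusters near the background limit what the arrays can show, and no background signal was analysed here.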

Other observations

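The tests of the hypothesis in this part, of the genes called after hepatectomy in the other models, were chosen only after the result was seen.

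In polysome RNA after hepatectomy, lists of hepatocyte metabolism, mTOR components, immediate early genes and heat shock proteins also differed with rapamycin. Among 35 genes of mature hepatocyte metabolism 2 rose and 2 fell (6 and 3 adjusted over the list alone), with a median of 0.14, Gls2, the liver glutaminase, at 0.67 and Mat1a, which makes the methyl donor S-adenosylmethionine, at 0.54. The camera adjusted p of that list was 0.0149 (adjusted p = 0.577 with an estimated correlation), 0.38 without DMSO 3, 0.0563 without rapamycin 2 and 0.25 under loess. Among 25 mTOR pathway components 2 fell (2 adjusted over the list alone), Ddit4 (−0.73) and Sesn3 (−0.68), both inhibitors of mTOR complex 1, with a median of −0.16. Their camera adjusted p was 0.021 (adjusted p = 0.48 with an estimated correlation) and 0.0979 without DMSO 3. Immediate early genes had a median of 0.32, with 1 that rose among all genes and 4 adjusted over the list alone. Their camera adjusted p was 0.0111 (adjusted p = 0.48 with an estimated correlation), 0.0765 without DMSO 1 and 0.105 without rapamycin 1. Heat shock genes had a median of −0.27, Hsf1, the transcription factor of the heat shock response, fell by 0.44, and 2 passed adjusted over the list alone. Their camera adjusted p was 0.00641 (adjusted p = 0.48 with an estimated correlation) and 0.0769 without rapamycin 3, and the median was −0.16 without DMSO 2.

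Some per-liver values followed the replicate number in fetuses. Erythroid markers in polysome RNA averaged 12.26, 12.44, 11.54 and 11.29 in DMSO 1, 2, 3 and 4, and 12.32, 12.46, 11.46 and 11.46 in rapamycin 1, 2, 3 and 4. Pck1 stood in total RNA at 6.84, 6.7, 10.38 and 9.47 in the DMSO livers and at 6.99, 6.68, 9.31 and 7.89 in the rapamycin livers. What the number stands for is not given in the sources used here. In the fasted/refed model G6pc1, the last enzyme of gluconeogenesis, stood at 7.13 and 7.70 in polysome RNA of DMSO 3 and rapamycin 2 and between 9.68 and 10.01 in the other 4 livers.

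Across transcript clusters, which are not independent replicates, the rapamycin effects in polysome and total RNA correlated at 0.886 after hepatectomy, where other splits of the livers gave 0.567 to 0.815. The correlation was 0.549 in the fasted/refed model (other splits 0.291 to 0.865) and 0.391 in fetuses (−0.00991 to 0.764).

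The hypothesis was tested that rapamycin shifts the genes called after hepatectomy the same way in the other models, by a score per liver, the mean of transcript clusters that rose minus the mean of those that fell. Of the 445 transcript clusters that fell in polysome RNA after hepatectomy, 71.2% were lower in the fasted/refed model (median −0.14) and 77.1% in fetuses (median −0.09), and of the 245 that rose 88.6% (median 0.21) and 65.3% (median 0.06) were higher. Of the 384 that fell in total RNA, 50.5% were lower in the fasted/refed model, with a median of −0.005 (quartiles −0.186 and 0.227), and 72.4% in fetuses (median −0.07). That median decides nothing, since members went both ways and 79 of the 384, like 55 of the 445, lay under the filter of 6.7 in fasted/refed DMSO livers. A fall may not show at such dim levels, which limits the score as well. Of the 160 that rose there, 78.8% (median 0.25) and 63.7% (median 0.06) were higher. In polysome RNA the score was 0.786 ± 0.0474 (SD, n = 3) with DMSO and 1.16 ± 0.0872 with rapamycin in the fasted/refed model, with no overlap of livers and an exact permutation p of 0.1, the smallest the design allows. In fetuses it was −0.462 ± 0.37 (SD, n = 4) and −0.305 ± 0.314, with an exact permutation p of 0.514 over unpaired livers. Within the 4 pairs of equal number it was higher with rapamycin in 4 of 4, by 0.15, 0.279, 0.182 and 0.0142, with an exact p of 0.125 by sign flips, the smallest they can give. None of these tests decides the hypothesis, which may hold in either model. In total RNA the same score differed by 0.25 in the fasted/refed model (exact permutation p = 0.1) and by 0.134 in fetuses (exact permutation p = 0.629 unpaired; 0.375 by exact sign flips, higher in 3 of 4 pairs).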
